A study of Homo sapiens with 6 samples.

How the data were processed

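The data are 6 RNA sequencing libraries of human prostate cancer cells labelled LNCaP. The labels put 3 libraries in a group transfected with a vector that overexpresses VIM-AS1, a long noncoding RNA antisense to the vimentin gene VIM, and 3 in a group given the pcDNA3.1 vector, a plasmid used here as the control. Each library was built from 1.3 µg of total RNA, per the labels' protocols, which do not name the library kit as one that marks strand. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

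Reads were trimmed with fastp, aligned with HISAT2 to hg38 and counted per gene with featureCounts, per the submitters' processing notes, which give no version of these tools. The annotation and the strand setting of the counting were not given in the sources used here. The values deposited for each library are a signal per gene, namely gene counts divided by 1 factor per library, and not raw counts. In every library 100% of the 25969 values were whole multiples of a single step within 0.01 read, with a largest distance of 6.57e-05 read. The reciprocal of the step equalled the median-of-ratios size factor that DESeq2 computes from the recovered reads, with factors from 0.819 to 1.27. The step that made these normalized values was not stated in the sources used here.

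Recovered reads per library numbered 17327906, 19889745 and 14762893 for VIM-AS1 overexpression replicates 1 to 3, and 17832055, 15979326 and 17967291 for control replicates 1 to 3. A gene with 0 reads in a library could hold up to 3 reads' worth of signal, or 0.151 to 0.203 CPM depending on the library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. No library pair within a group agreed within sampling noise, with a chi-square per degree of freedom from 7.14 to 69.2 over genes with at least 20 reads in the pair, so all 6 libraries were counted separately.

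Gene identifiers were matched to symbols for 99.3% of genes (25776 of 25969). Positions, transcript lengths and GC contents came from GENCODE 29 on GRCh38. The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend and empirical Bayes moderation on log2(value + 1), for the 20927 genes with a mean value of at least 1 over the 6 libraries. The design written before the data were examined named edgeR's quasi-likelihood test for raw counts and this limma test for normalized values, and the deposited unit decided between them. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with camera on the same log2 values with a preset correlation of 0.01, with an estimated correlation, and with fry. The 24 lists were fixed before the data were examined, lists with at least 5 tested members were tested, and 7 genes belong to more than 1 list. Counts of list members were also adjusted over the list alone.

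The third library of each group stood apart from the other two of its group, as described with the results. A limma fit with a batch term for the third libraries was therefore added after the data were seen, and its values stand beside those of the main test. Also added then were edgeR's quasi-likelihood test (version 4.0.16) on the recovered reads and a correction that removed each library's spline trends with GC content and transcript length, both spline terms having 5 degrees of freedom. GC content and length were known for 99.9% of tested genes. Alternatives listed before the data were examined were TMM and library size scaling, no filter on low values, a filter of at least 10 reads in every library of a group, a pseudocount of 0.1, DESeq2 (version 1.42.0) and limma-voom on the recovered reads, a minimum absolute log2 fold change of 1, a block for the replicate number, and each library left out. The alternative of median-of-ratios scaling was identical to the deposited scaling and was not run separately.

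Genes were named by a rule fixed before the data were examined: a few genes always, among them VIM-AS1, VIM, HMGCS1, IGF2BP2 and KLK3, the 8 largest changes in each direction among genes past the threshold of the main test with non-overlapping groups, and up to 3 members of each list past that threshold. The same rule with the batch term, limited to means of at least 100 for the largest changes, was added after the data were seen. Other members of the lists and a few further genes were named after their values were seen.

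The fits were tested on simulated data: read counts were drawn for 14714 genes from the means and library sizes of this comparison, with 200 genes changed. With a simulated shift of the third libraries, made the same in both groups, limma without a batch term recovered 5% of genes changed by 1 log2 unit and 74% of those changed by 2 log2 units. With the term it recovered 92% and 100%, and 14 of its 206 calls were genes left unchanged. The simulated noise was taken from an edgeR fit with the term. The term was thus right by construction, so these values cannot tell whether it is right for the data, where the shift was only partly shared. Camera with the batch term called a simulated list of 21 genes raised by 0.7 log2 units, and 5 of 100 random lists were also under 0.05. The simulated genes were drawn independently, so this does not test the preset correlation for lists whose members vary together. The mitochondrially encoded list, for example, had an estimated correlation of 0.74 without the batch term. Genes with a mean value under 1, numbering 5042, were not tested.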

Results

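Gene expression was measured by RNA sequencing in 3 libraries of cells labelled LNCaP, an androgen-sensitive line from a lymph node metastasis of prostate cancer, that were transfected with a VIM-AS1 overexpression vector, and in 3 libraries with the pcDNA3.1 vector. The series asks how overexpression of VIM-AS1 affects gene expression. The libraries held 14762893 to 19889745 recovered reads. Values below are normalized read counts as deposited, given as mean ± SD over 3 libraries.

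VIM-AS1 was present at 2326 ± 388 normalized reads (SD, n = 3) in the overexpression libraries and at 5.13 ± 3.72 in the controls, a log2 fold change of 8.80 ± 0.46 (SE; limma, adjusted p = 1.62e-05). The interferon-induced gene OASL rose from 8.07 ± 2.75 to 173.1 ± 49.3, and SERPINE2, which encodes a secreted protease inhibitor, rose from 70.7 ± 6.76 to 274.6 ± 31.9. YPEL3, a gene linked to growth arrest, fell from 403.6 ± 75.7 to 65.5 ± 18.0, and BMF, which encodes a pro-apoptotic member of the BCL2 family, fell from 179.6 ± 19.0 to 39.1 ± 6.86. These 5 genes, 3 higher and 2 lower, were the ones past the threshold among 20927 tested by limma without a batch term. HMGCS1, the enzyme that makes HMG-CoA from acetoacetyl-CoA, stood at 1912 ± 824 against 658.9 ± 206, and did not pass this test (log2 fold change 1.50 ± 0.32, adjusted p = 0.095).

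**Figure D1:**
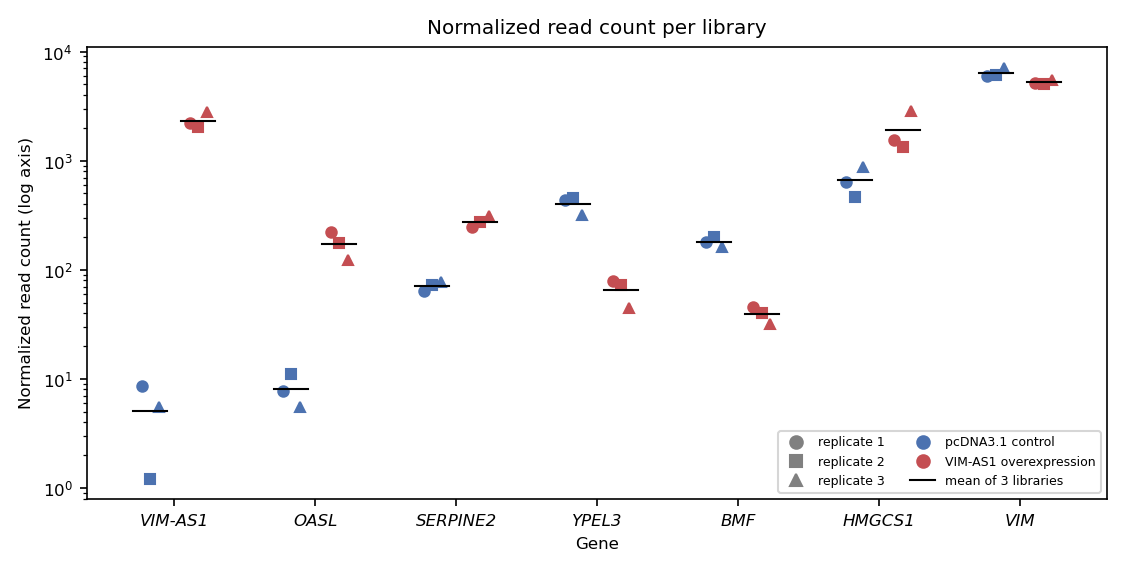
Normalized read count (log axis) of 7 genes in each library, with controls in blue, VIM-AS1 overexpression in red, the marker giving the replicate and black lines the mean of 3 libraries. VIM-AS1 lies between 2019 and 2763 in the overexpression libraries and between 1.22 and 8.63 in the controls.

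VIM-AS1 (ENSG00000229124) lies on the minus strand of chromosome 10 from 17214239 to 17229985 (GRCh38), and VIM (ENSG00000026025) on the plus strand from 17228259 to 17237593. Of the 1992 bp of VIM-AS1 exons, 641 bp (32.2%) are also exon of VIM on the opposite strand. The library kit is not named as one that marks strand, and the strand setting of the counting is not known. Reads from that part therefore cannot be assigned to either gene with certainty. Recovered reads of VIM-AS1 numbered 2085, 2061 and 2700 in the overexpression libraries and 9, 1 and 7 in the controls. VIM itself was at 5236 ± 258 in the overexpression libraries and 6393 ± 647 in the controls (log2 fold change -0.28 ± 0.20, limma adjusted p = 0.60), and with the batch term described next its adjusted p was 0.061. edgeR on the recovered reads with the same term gave an adjusted p of 0.035 for VIM.

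The third library of each group stood apart from the first and second. Over 13175 genes with a mean of at least 20, the deviations of the third libraries from their group means had a Pearson r of 0.84 across genes, and this shared deviation was correlated with GC content (Spearman rho -0.83 across 13168 genes). Genes are not independent replicates. The first and second controls did not form a tight pair either. Their chi-square per degree of freedom was 41.4, against 65.4 and 62.2 for their pairs with control replicate 3. In the VIM-AS1 group it was 7.14 for the first and second libraries, and 45.5 and 69.2 for their pairs with the third. Fold changes from the first and second libraries alone and from the third libraries alone had a Pearson r of 0.84 over 9758 genes with a mean of at least 100, with 81.9% of the same sign, and of 0.37 over all 20927 tested genes, with 71.4% of the same sign. With a batch term for the third libraries, added after the data were seen, limma called 2403 genes higher and 1662 lower. The balance was opposite among calls with an absolute log2 fold change of at least 1, with 168 higher and 684 lower. The 5 genes above were all among the 4065 called. Groups did not overlap in 2407 of the 4065, while over all tested genes 19.8% did not overlap, against 10% by chance for 3 against 3. Among genes called from the first and second libraries alone, the third libraries gave the same sign for 619 of 620 higher and 474 of 481 lower genes.

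Both counts changed when single libraries were left out, although VIM-AS1 and OASL passed without the term whichever library was left out. Without the term, limma called 41 genes when control replicate 3 was left out, 2 without control replicate 1 or control replicate 2 and 3 without VIM-AS1 replicate 2, and TMM and library size scaling gave 4 higher and 12 lower, and 15 higher and 13 lower. With the term, 288 genes were called without VIM-AS1 replicate 3, 618 without control replicate 3 and 2591 without VIM-AS1 replicate 2. In the paragraphs below, "rose" and "fell" stand for an adjusted p under 0.05 in limma with the batch term, and SE values come from that fit. Its p-values and SE values measure the spread left after the shift of the third libraries is removed. That shift was picked from these same data, so both may be too small. Of the 20927 tested genes 4065 were called in that fit, the share against which counts of list members are to be read. No gene other than the 5 above passed in the main limma test, which has no batch term.

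**Figure D2:**
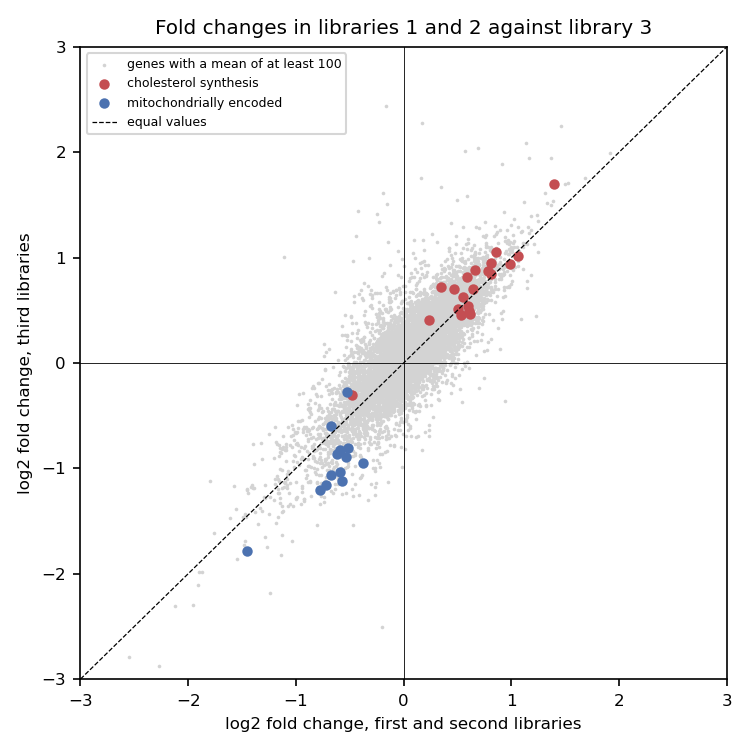
Log2 fold change of VIM-AS1 overexpression over control from the first and second libraries (horizontal axis) and from the third libraries (vertical axis) for genes with a mean of at least 100 (grey), with cholesterol synthesis genes in red, mitochondrially encoded genes in blue and a dashed line of equal values. VIM-AS1, at 8.83 and 8.73, lies outside the axes, and Pearson r across the genes plotted is 0.84, against 0.37 over all tested genes.

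Among abundant genes, the largest rises after VIM-AS1 and SERPINE2 were those of THSD4 (log2 fold change 1.72 ± 0.19), the ETS transcription factor ETV4 (1.71 ± 0.13), the actin-binding gene TAGLN (1.59 ± 0.13), the fatty acid binding gene FABP5 (1.56 ± 0.23) and TFRC, the transferrin receptor of iron uptake. TFRC rose from 2308 ± 593 to 6912 ± 2340 (SD, n = 3; log2 fold change 1.56 ± 0.11, limma with the batch term, adjusted p = 3.44e-08). Among genes with a symbol and a mean of at least 100, the deepest falls besides YPEL3 and BMF were those of CHAC1, a glutathione-degrading enzyme of the integrated stress response (-1.98 ± 0.17), ODAD3 (-1.93 ± 0.20), the ectonucleotidase gene ENTPD2 (-1.91 ± 0.13), the noncoding RNA NALT1 (-1.71 ± 0.16), RGS11 (-1.65 ± 0.13) and LMO1 (-1.57 ± 0.15). Each of these genes was chosen with non-overlapping groups. Its same direction in the first and second libraries and in the third was fixed by that choice and is no separate evidence. Of the 78 named genes called with the batch term, 43 lost the call when VIM-AS1 replicate 3 was left out, 30 without control replicate 3 and 10 without VIM-AS1 replicate 2.

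Cholesterol synthesis genes rose as a group. Among the 24 lists camera called 10 without the batch term and 8 with it, against 1 and 0 with an estimated correlation, while fry, which does not compare a list with other genes, called 7 and 12. Of 21 tested members, 19 rose, GGPS1 fell and SC5D did not pass, and the counts adjusted over the list alone were the same. Besides HMGCS1 (log2 fold change 1.50 ± 0.12, 1.40 in the first and second libraries and 1.70 in the third), they included SQLE (0.97 ± 0.10), ACAT2 (1.05 ± 0.10) and CYP51A1 (2.11 ± 0.29). The list's median log2 fold change was 0.66, with 0.62 in the first and second libraries and 0.73 in the third. Camera gave an adjusted p of 1.32e-11 without the batch term and 6.96e-17 with it. With an estimated correlation the adjusted p was 0.043 without the term and 0.13 with it. The correlation estimated for this list without the term was 0.0076, under the preset of 0.01. A higher correlation therefore does not account for that larger p-value. In this form camera takes its degrees of freedom, for every list, from the residuals, 4 without the term and 3 with it. Without the term no member passed over all genes, and 11 rose when adjusted over the list alone by limma. The published work on this RNA concerns HMGCS1, so the direction of this list is not independent evidence.

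**Figure D3:**
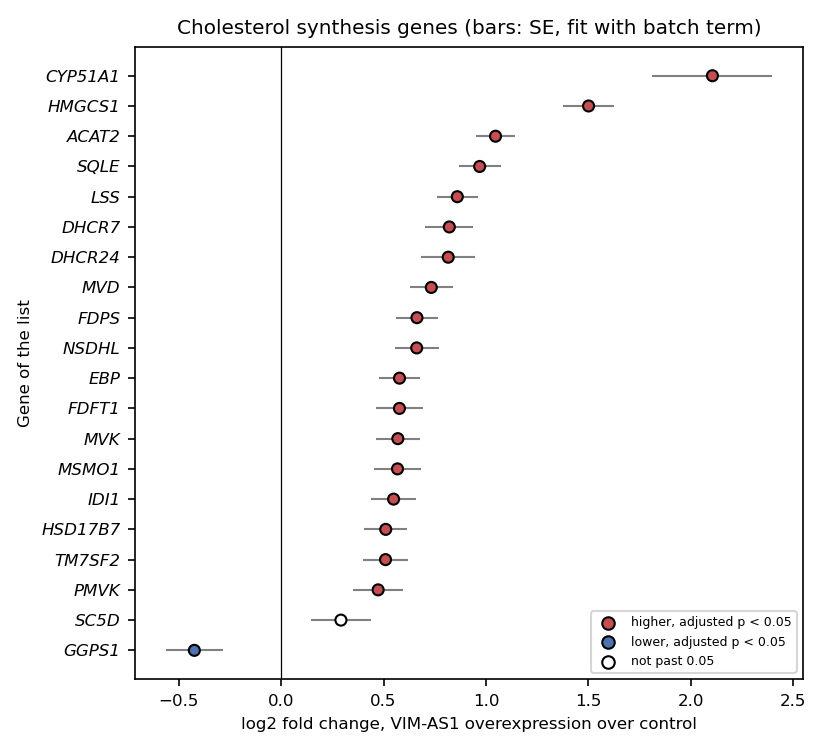
Log2 fold change of VIM-AS1 overexpression over control (horizontal axis) for 20 of the 21 tested genes of cholesterol synthesis, with SE bars from limma with the batch term and fill colours for genes past the threshold. The higher members lie between 0.47 (PMVK) and 2.11 (CYP51A1), and GGPS1 lies at -0.42.

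Fatty acid synthesis genes rose in part, and genes of sterol transport went both ways. Of 15 tested fatty acid synthesis genes 8 rose and none fell, both over all genes and adjusted over the list alone, among them the citrate lyase ACLY (9730 ± 885 against 4781 ± 758), ACSS2 (log2 fold change 0.91 ± 0.11), FADS2 (0.74 ± 0.11) and the synthase FASN (0.67 ± 0.14). Their median was 0.37, with a camera adjusted p of 0.000821 without the batch term and 0.000106 with it, and adjusted p = 0.12 and 0.28 with an estimated correlation. Of 16 genes of sterol uptake, export and sensing, 4 rose and 2 fell (4 and 3 adjusted over the list alone). SCARB1 (0.50 ± 0.11), which encodes a receptor of high-density lipoprotein, was among those that rose, and the sterol exporter ABCG1 fell (52.3 ± 15.4 against 120.6 ± 13.8). This list had a median of 0.12 and a mean of -0.07, and camera did not call it (adjusted p = 0.59 without the term and 0.42 with it). The mean share of mitochondrially encoded reads was lower in the same libraries in which these lipid genes were higher, at 6.50% against 11.6%.

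Many cell division genes rose with VIM-AS1 overexpression. Of 38 mitosis and G2/M genes 22 rose and CENPF fell (24 and 1 adjusted over the list alone), including CCNA2 (812.8 ± 385 against 385.2 ± 119), the survivin gene BIRC5 (log2 fold change 0.99 ± 0.11), PLK1 (0.94 ± 0.13) and CCNB1 (0.75 ± 0.10). The list's median was 0.39, with 0.37 in the first and second libraries and 0.40 in the third. Camera gave adjusted p = 5.29e-07 without the batch term and 8.22e-10 with it, against adjusted p = 0.12 and 0.13 with an estimated correlation. Of 34 replication and S phase genes 13 rose, E2F1 and CDT1 fell and 19 did not pass (15 and 2 adjusted over the list alone), with TYMS (0.78 ± 0.11) and RRM2 (0.75 ± 0.11) among the higher ones. Camera gave adjusted p = 0.00351 and, with the term, 0.00217, and adjusted p = 0.12 and 0.28 with an estimated correlation. Of 19 replication-dependent histone genes H2BC11 and H2BC12 rose and 17 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.26 and 0.42).

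Several chaperone genes of the cytosol and of the endoplasmic reticulum rose. Of 17 heat shock genes 10 rose, none fell and 7 did not pass, among them HSPA1A and HSPB1 with negative values, while 13 rose and 1 fell adjusted over the list alone. The largest rises were those of FKBP4 (log2 fold change 1.04 ± 0.10) and HSPA8, a constitutive HSP70 chaperone (23231 ± 3845 against 11349 ± 1124). Their median was 0.46, and camera gave adjusted p = 0.000325 without and 8.21e-06 with the batch term, with adjusted p = 0.12 and 0.22 under an estimated correlation. Of 30 genes of the unfolded protein and integrated stress responses 10 rose, 3 fell and 17 did not pass (11 and 3 adjusted over the list alone). The members that rose included the chaperones and folding factors HYOU1 (1.07 ± 0.11), CALR (1.04 ± 0.11) and HSPA5 (0.78 ± 0.11), and also PSAT1 (0.40) and PPP1R15A (0.32), while CHAC1, DDIT3 (-0.77 ± 0.22) and CEBPB fell and ATF4, ASNS and TRIB3 were among those that did not pass. Camera called this list upward (adjusted p = 0.0131 without and 0.00368 with the term), with adjusted p = 0.35 and 0.28 under an estimated correlation.

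Some hypoxia and glycolysis genes rose, and most mitochondrially encoded transcripts fell. Of 31 hypoxia and glycolysis genes 13 rose, 2 fell and 16 did not pass, GAPDH, PKM, ENO1 and ALDOA among these, while 14 rose and 2 fell adjusted over the list alone. The kinase HK2 rose from 433.1 ± 23.1 to 924.9 ± 132, and PGAM1 (log2 fold change 0.82 ± 0.12), PFKFB4 (0.64 ± 0.11) and LDHA (0.46 ± 0.13) rose, whereas the hypoxia-induced carbonic anhydrase CA9 fell (-0.78 ± 0.14). Camera gave adjusted p = 0.000773 without and 0.000106 with the term, and adjusted p = 0.35 and 0.28 with an estimated correlation. All 13 mitochondrially encoded genes had negative values and 10 of them fell (13 adjusted over the list alone), among them MT-CO2 (-0.92 ± 0.27), MT-ND5 (-0.61 ± 0.16) and MT-ATP8 (-1.57 ± 0.19). Their median was -0.70, and over same-numbered libraries the medians were -0.24, -1.08 and -0.95. Camera gave adjusted p = 1.48e-05 without and 3.77e-07 with the term, but adjusted p = 0.40 and 0.28 with an estimated correlation, and fry did not call the list (adjusted p = 0.16 and 0.0517). All genes with a symbol starting in MT-, a wider set than this list, made up 7.06%, 6.86% and 5.57% of reads in the overexpression libraries. In the controls they made up 8.73%, 14.3% and 11.8%, with no overlap between groups (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). Of 42 nuclear-encoded oxidative phosphorylation genes CYC1 rose, COX6C fell and 40 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.56 and 0.66).

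Interferon-stimulated and immediate early genes moved in both directions, and 3 inflammatory genes rose. Of 32 interferon-stimulated genes 6 rose and 5 fell (10 and 5 adjusted over the list alone). OASL (4.27 ± 0.28), OAS3 (2057 ± 45.1 against 787.7 ± 105, log2 fold change 1.39 ± 0.11) and ISG15 (0.63 ± 0.10) rose, and IFI27 (-1.33 ± 0.41) and IFITM1 (-1.07 ± 0.26) fell. Camera called the list upward without the batch term (adjusted p = 0.00525) and not with it (adjusted p = 0.065), and the adjusted p was 0.12 and 0.28 with an estimated correlation. Of 17 NF-kB and inflammatory genes RELB (1.44 ± 0.14), NFKB1 (0.82 ± 0.12) and ICAM1 (0.58 ± 0.14) rose and none fell, the same when adjusted over the list alone. Camera gave adjusted p = 0.0231 without the term and 0.0651 with it, and adjusted p = 0.30 and 0.28 with an estimated correlation. The share of NF-kB and inflammatory genes called with the term was close to that of all tested genes (4065 of 20927). Of 20 immediate early genes 5 rose and 7 fell (6 and 8 adjusted over the list alone), with FOS (-0.67 ± 0.10), FOSB (-1.03 ± 0.15) and JUNB (-0.74 ± 0.10) lower and CCN2 (0.72 ± 0.11) higher (camera adjusted p = 0.61 and 0.36).

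**Figure D4:**
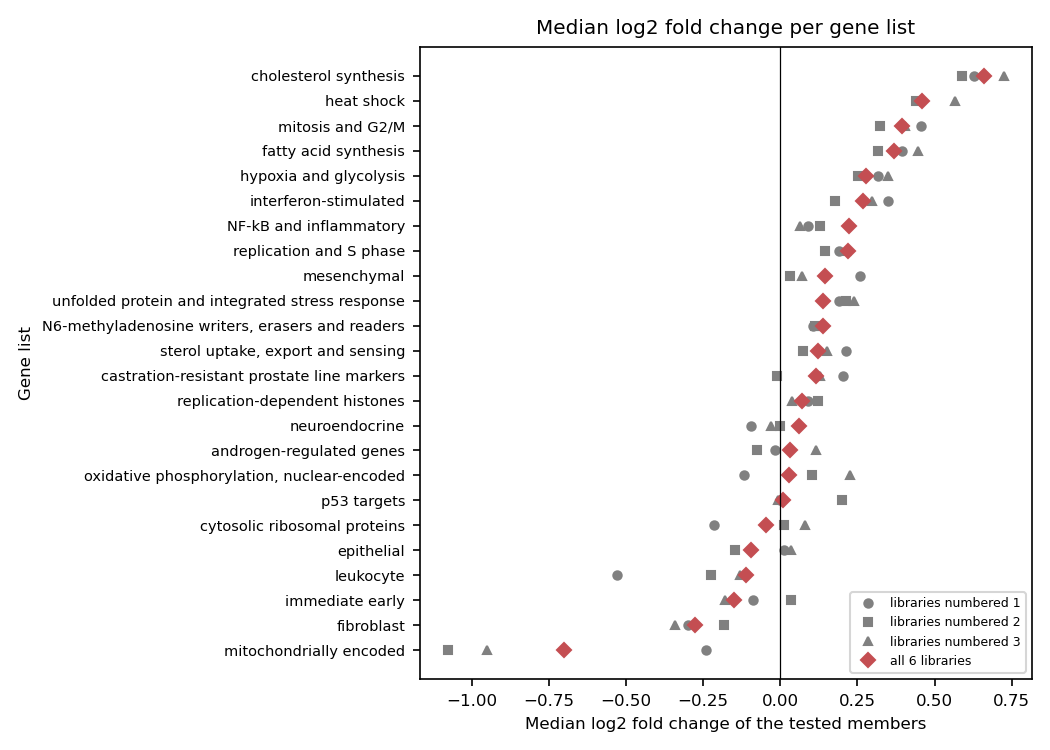
Median log2 fold change of VIM-AS1 overexpression over control (horizontal axis) for the tested members of 24 gene lists, over all 6 libraries (red) and over each pair of same-numbered libraries (grey). Medians run from -0.70 for mitochondrially encoded genes to 0.66 for cholesterol synthesis.

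The lists for cell state and identity were not called by camera, with or without the batch term. By fry, which tests whether genes move on balance in 1 direction, the neuroendocrine list was called lower (adjusted p = 0.00302 without and 0.00838 with the term), the mesenchymal list higher (0.033 and 0.0347) and the fibroblast list lower with the term (0.00722, and 0.18 without it). Of 23 tested androgen-regulated genes 5 rose, including FKBP5 (0.77 ± 0.13), and 3 fell, the same when adjusted over the list alone (adjusted p = 0.58 and 0.42), and the median of 0.03 and mean of -0.01 of that list differed in sign. Of 17 epithelial genes ESRP2 and ST14 rose and CLDN4 and CDH3 fell, the same when adjusted over the list alone (adjusted p = 0.94 and 0.62). Of 22 mesenchymal genes TAGLN, TNC and FN1 (0.49 ± 0.14) rose and 1 gene fell, with 4 and 2 adjusted over the list alone (adjusted p = 0.19 and 0.27). With the batch term 3 mesenchymal genes rose and 2 fell under TMM scaling, and 2 rose and 3 fell under library size scaling. With the deposited scaling the share of mesenchymal genes called was close to that of all tested genes (4065 of 20927). Of 11 neuroendocrine genes the synaptophysin gene SYP fell, over all genes and adjusted over the list alone, from 61.9 ± 10.4 to 13.6 ± 3.77, while the list's median of 0.06 and mean of -0.40 differed in sign (adjusted p = 0.36 and 0.45). Besides SYP, only SOX2, SRRM4, NCAM1 and FOXA2 had negative values. They averaged 2.45 to 10.7 normalized reads in the controls and did not pass. The remaining members had positive values, with DLL3 at 0.11, ENO2 at 0.09 and EZH2 at 0.06 the most abundant of them. Of 16 markers of the PC-3 and DU145 prostate lines 5 rose, among them KRT7 (1.03 ± 0.12) and MET (0.74 ± 0.13), and 2 fell (5 and 4 adjusted over the list alone; adjusted p = 0.31 and 0.27). Of 8 fibroblast genes THY1 rose and DCN (-1.30 ± 0.16), PDGFRB and COL1A1 fell (1 and 4 adjusted over the list alone; adjusted p = 0.23 and 0.065). Of 8 leukocyte genes CSF1R fell, and none passed when adjusted over the list alone (adjusted p = 0.24 and 0.33).

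Among 21 N6-methyladenosine writers, erasers and readers METTL16 (0.52 ± 0.11), IGF2BP1 (0.44 ± 0.11), YTHDF2 (0.42 ± 0.10) and HNRNPC rose and 17 did not pass, the same when adjusted over the list alone (camera adjusted p = 0.0801 and 0.065). IGF2BP2, a reader of this mark, was at 79.6 ± 22.1 against 85.2 ± 18.1 and did not pass (log2 fold change -0.11 ± 0.20, limma with the term, adjusted p = 0.76). Of 27 p53 targets AEN, TP53I3, POLH and PHLDA3 rose and CCNG1 and BBC3 fell, the same when adjusted over the list alone (adjusted p = 0.30 and 0.45). The called shares of the N6-methyladenosine list and of the p53 list were close to that of all tested genes (4065 of 20927). Of 59 cytosolic ribosomal protein genes RPS23 fell and 58 did not pass, with none adjusted over the list alone (adjusted p = 0.67 and 0.33). With the batch term, 3 of the N6-methyladenosine genes rose with TMM scaling and 1 with library size scaling, and 2 p53 targets rose with the latter. With library size scaling and the batch term 6 ribosomal protein genes fell and camera called the list lower (adjusted p = 0.0132).

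In all 6 libraries the transcripts of several prostate luminal genes were close to 0. KLK3, which encodes prostate-specific antigen, had 2 reads in control replicate 1 and none in the other 5 libraries, and its mean was too low for it to be tested. STEAP1 had 2 reads and FOLH1 and PCA3 had 6 reads each over the 6 libraries, while SLC45A3 averaged 70.7 normalized reads. At the other end, VIM averaged 5814 normalized reads, CD44 2488, EGFR 2104 and AXL 1624, and the keratin gene KRT8 averaged 78354 against 55.1 for EPCAM.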

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

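The batch term, edgeR, the correction for GC content and length, fry with the term and every alternative to the result with the batch term were chosen after the data were seen. Without a batch term, the 5 genes called by limma became 16 with TMM scaling, 28 with library size scaling, 17 without a filter, 341 with DESeq2, 3 with limma-voom and 3 with edgeR on the recovered reads. The 5 genes were all past the threshold in the TMM, unfiltered and DESeq2 results, and SERPINE2 and BMF were not with edgeR (adjusted p = 0.0599 and 0.0583) or limma-voom (0.0604 and 0.05003), nor SERPINE2 with library size scaling (0.0550). With libraries left out the count ran from 2 to 41. Removing trends with GC content and length gave 2279 genes and the batch term 4065, and each kept all 5. The number of list members called was 1, and 3 with TMM scaling, 7 with library size scaling, 3 without a filter, 26 with DESeq2, 250 with a replicate block, 111 after the GC and length correction and 189 with the batch term, and ran from 1 to 4 with libraries left out. With a minimum absolute log2 fold change of 1 the 5 genes all stayed. With the batch term, the fold threshold left 852 of 4065 genes, 168 higher and 684 lower, and libraries left out gave from 288 to 4493. When the third library of either group is left out, the remaining one stands alone in its batch and adds nothing to the contrast, which leaves 4 libraries. Causes of the other moves were not tested.

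The replicate numbers were not treated as pairs. Over the 20927 tested genes the deviations of same-numbered libraries had correlations of 0.09, 0.26 and 0.41 across genes, the first under the bound of 0.1 set beforehand, although every library correlated best with its own number. Over genes with a mean of at least 20 they were 0.32, 0.72 and 0.84, and VIM-AS1 replicate 1 then correlated best with control replicate 2 (0.42). A replicate block in limma gave 5571 genes, 3315 higher and 2256 lower.

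VIM-AS1 passed the threshold under every setting, with log2 fold changes from 8.18 to 9.24. Camera called 10 lists, 1 with an estimated correlation, none (0) with an estimated correlation and the batch term, and 7 to 11 under the other settings, while fry called 7, and 12 with the batch term. The median of the cholesterol synthesis list stayed positive under all 17 alternatives. The batch term, the replicate block and the filter changes do not alter the members' fold changes and left it at 0.66, so they are no separate evidence. IGF2BP2, not called in any of these fits, changed sign from -0.11 to 0.0518 without VIM-AS1 replicate 2 and to 0.0531 without control replicate 3, within a range of -0.32 to 0.05 over libraries left out. With the batch term no named gene changed sign, 93 combinations of gene and setting lost a call and 8 gained one. Scaling moved the median of all genes from -0.02 to -0.06 with TMM and -0.08 with library size. Depth limits genes near 3 reads, such as KLK3, for which no difference was detectable.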

Other observations

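The tests of sequencing depth, of a single aberrant library and of cell identity below were chosen after the result was seen, as was the batch term, and the spread in the test of FOXO-linked genes was added after its value was seen. Most listed genes of ribosome production in the nucleolus rose with VIM-AS1 overexpression. Of 17 such genes listed for this test, 12 rose and none fell in limma with the batch term, among them DKC1 (2800 ± 162 against 1648 ± 4.60 normalized reads, SD, n = 3), NOP56 (log2 fold change 0.59 ± 0.10, SE) and NCL (0.62 ± 0.12), while NPM1, FBL and GNL3 did not pass. Of 8 tested feedback and target genes of ERK signalling, 6 rose, namely ETV5 (1.56 ± 0.29), DUSP4 (1.08 ± 0.22), CCND1 (0.76 ± 0.10), SPRY2, PHLDA1 and EPHA2. Immediate early genes that also respond to ERK signalling went both ways, with EGR1 (-0.47), FOS (-0.67), FOSB (-1.03) and JUNB (-0.74) lower and FOSL1 (0.75) and DUSP1 (0.34) higher. IRS2 rose (0.92 ± 0.10), and KLHL24 (-1.36 ± 0.16) and FBXO32 (-0.97 ± 0.17) fell.

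These lists were written to test hypotheses about the leading genes. ETV4 and ODC1, the latter at 5780 ± 530 against 2356 ± 304, may reflect higher output of the ERK pathway, whose genes had a median log2 fold change of 0.90 (camera with the batch term, p = 5.39e-06, and p = 0.0182 with an estimated correlation). Immediate early genes, which went both ways, do not decide it, and that reading stays open. ETV4 and ODC1 may also reflect higher nucleolar and MYC-linked biosynthesis, whose genes had a median of 0.59 (p = 9.36e-11, and p = 0.0541 with an estimated correlation). Lower output of FOXO and quiescence-linked transcription could account for the lower BMF, YPEL3, TXNIP and TSC22D3, but its 15 genes had a median of -0.19 ± 0.18 (SE) with members in both directions (camera p = 0.0955, and 0.346 with an estimated correlation). By the bound of -0.2 alone this would argue against that reading, and with the spread counted it decides nothing. MYC itself was at a log2 fold change of -0.11 and did not pass with the batch term (adjusted p = 0.51).

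The third library of each group deviated from the first and second in a shared direction. Removing trends with GC content and transcript length took out 70.9% of the variance of that direction, yet the third libraries' deviations still had a correlation of 0.55 (0.84 before), so these trends may be a large part of the pattern but were not the whole of it by the bound of 0.5 set beforehand. Sequencing depth went opposite ways, with the third control library at 1.06 times the mean of the first and second and the third VIM-AS1 library at 0.79 times, which argues against depth. A separate day of culture or library preparation stays open and untested, since the labels name none.

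Cholesterol synthesis genes were higher in the overexpression libraries. Trends with GC content and transcript length argue little for it, since the list's median was 0.65 after their removal (0.66 before). One aberrant library also does not account for it, because the lowest of the 3 medians over same-numbered libraries was 0.59. An effect of VIM-AS1 is a candidate explanation, as is any other difference between the transfections, such as cell density at harvest, and neither was tested.

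Several prostate luminal transcripts were near 0 in all 6 libraries, which may mean a cell line other than the label says: 6 luminal genes listed for this test, among them KLK3, FOLH1, STEAP1, PCA3 and SLC45A3, had a median percentile of 18.9 among the genes analysed. LNCaP cells grown without androgen would be expected to keep FOLH1, which lay at the percentile 20.1. A mixture with a large share of LNCaP cells is argued against by KLK3, whose highest level was 0.112 CPM. The comparison of the groups does not depend on the name of the line, and no genotype was examined.

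The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05 for any result. Without a batch term the real division gave 5 genes and the highest of the others 1. For lists called by camera the counts were 10 and 6. Without the term, only the real division of the 10 reached these counts. With the term the real division gave 4065 genes, and each other division with 1 replicate 3 library per group gave 0. The remaining divisions put both replicate 3 libraries in 1 group, so their contrast with the term rests on 1 library against 3. In every division except the real division, a difference between VIM-AS1 and control libraries adds to the residual spread. Lower counts there are therefore partly set by the design, and they do not decide whether the real result exceeds chance.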
